A study of Mus musculus with 8 samples.

How the data were processed

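Messenger RNA was measured by sequencing in 8 libraries of macrophages grown from mouse bone marrow. Per the labels, marrow was taken from 3 mice of each genotype, DNMT3A-HET or wild type (WT), all male and 13 weeks old, and was cultured with M-CSF at 50 ng/mL. IL-6 at 10 ng/mL was added to a part of the cultures on day 6 for 2 days, and RNA was collected on day 8. Libraries were made with a stranded kit for polyadenylated RNA. The labels give 2 libraries, numbered 1 and 2, for each of the 4 combinations of genotype and treatment. They do not say which mouse gave which library or whether mice were pooled, so p-values here measure the spread between these libraries, which may be partly technical. The deposited column names join the number to the genotype in both treatments, so same-numbered libraries of a genotype may share a mouse. Control and IL-6 libraries of a genotype would then not be independent.

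The values analysed were the raw gene counts that the authors deposited as a table with 55376 genes and 8 columns of libraries. The submitters' processing notes name fastp 0.12.4, STAR 2.7.9a, SAMtools 1.9, featureCounts 1.6.2 and the genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene could therefore not be told from those of a gene that overlaps its exons, and such genes are called uncertain. Every column was matched to its library by its name. The coordinates in the deposited table matched the gene models of annotation release M21 for 99.8% of genes, which gave exon length and GC content. The table held 26 gene symbols that a spreadsheet had turned into dates, of which 25 were restored by position and 1 was left unresolved.

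Total counts per library ran from 18926641 to 50137897. A floor of 3 counts corresponded to 0.0598 to 0.159 library-scaled counts (CPM). No pair of libraries of a group agreed within sampling noise, and none was counted as a repeat of another. The chi-square per gene between the libraries of a group was 19.3 in WT control, 13.3 in WT IL-6, 6.66 in HET control and 6.91 in HET IL-6. In the same order, the median size of their log2 difference was 0.18, 0.16, 0.10 and 0.089.

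Differential expression was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 over the groups, which left 13721 genes, and libraries were scaled by TMM. A quasi-likelihood F test was fitted to all 8 libraries with 1 mean for each group, robust dispersion estimates and 4 residual degrees of freedom. The spread of a gene was estimated over all groups together, although libraries of a WT group differed more than those of a HET group. Within WT p-values may therefore be too small, and within HET too large. The tests were 2-sided, and p-values were adjusted over the tested genes by the Benjamini-Hochberg method. A gene was called when its edgeR adjusted p was under 0.05. The comparisons were IL-6 against control in WT, in HET and averaged over genotype, HET against WT in control, in IL-6 and averaged over treatment, and the difference of the IL-6 response between the genotypes. Log2 fold changes are given with their standard error, and CPM values are scaled by TMM and given as mean ± SD over 2 libraries.

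Named genes followed a rule fixed before the data were examined. Dnmt3a, Socs3, Bcl3, Stat3, Il6ra, Il6st, Il4ra, Tnf, Il1b, Il6, Ccl2 and Arg1 could be named in any comparison. In addition, the rule took the 10 genes that rose and the 10 that fell by the most among called genes with a group mean of at least 5 CPM and no overlap in CPM between the libraries compared. For an averaged comparison the libraries had to be apart, in the same direction, within each genotype or each treatment. For the IL-6 comparisons within a genotype and for the difference of responses the number was 5 each way, and for the latter the overlap was not considered. Predicted gene models were not named. Of each gene list described, up to 4 members with the smallest p could be named.

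Gene lists were also fixed before the data were examined, 18 of pathways and 12 of cell types. The pathway lists covered DNA methylation, IL-6 and STAT3 signalling, proinflammatory mediators, type I interferon-stimulated genes, alternative activation, MHC class II, MHC class I, lipid handling, cholesterol synthesis, the cell cycle, glycolysis, oxidative phosphorylation, lysosomes, osteoclast genes, the unfolded protein response, NRF2 targets, phagocytic receptors and matrix remodelling. The cell type lists covered macrophages, monocytes, neutrophils, dendritic cells, B cells, T and NK cells, mast cells and basophils, erythroid cells, megakaryocytes, stromal cells, endothelial cells and adipocytes. The 24 lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. With the estimated correlation camera called 0 lists in each of the 7 comparisons. The lists that passed an unadjusted p of 0.05 with it numbered from 0, in HET against WT averaged over treatment, to 5, in IL-6 against control in HET.

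The procedure was tested on simulated data with known changes, drawn with the gene means, spreads and library totals of the real libraries. In the simulation of HET against WT in control, run on 13442 genes, 66.0% of genes changed 1.5-fold and 75.5% of genes changed 2-fold were called. For IL-6 against control averaged over genotype, run on 13462 genes, the shares were 74.2% and 86.6%. For the difference of responses, run on 13475 genes, they were 30.2% and 68.4%. Among all calls, 13 of 151, 8 of 164 and 5 of 101 were of genes not changed in the simulation. A list raised in the simulation was called, and 0 of the other lists were called by camera or by fry. Simulated genes were drawn independently of each other, without a GC trend and with the same spread in all groups, unlike the real genes. The simulation therefore does not test whether the preset correlation of camera suits the real lists. With 2 libraries in a group, a gene that missed the threshold is not shown to be unchanged.

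Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in 4 libraries, the library number or the combination of genotype and number as a block, a fit to the compared groups alone, counts summed by genotype and number, and leaving out each library in turn. Alternatives chosen after seeing the data were the removal of each library's trend on GC content and exon length through offsets (splines with 5 degrees of freedom), thinning of all libraries to the smallest total, leaving out the HET libraries of 1 number with and without those offsets, a crossed pairing of the WT libraries and scaling to total counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.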

Results

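The series measured gene expression in macrophages differentiated from the bone marrow of mice, which were wild type (WT) or carried the genotype label DNMT3A-HET (HET). Dnmt3a encodes a de novo DNA methyltransferase. The macrophages were left as controls or exposed for 2 days to IL-6, an inflammatory cytokine that signals through STAT3, and the series title names a reduction of DNMT3A in blood cells as its subject. The comparisons address how these macrophages responded to IL-6, how HET differed from WT, and whether the response differed between the genotypes. Each of the 4 groups held 2 libraries, and RNA was collected on day 8. Gene counts totalled 18926641 to 24881197 in all libraries other than HET IL-6 number 2, which held 50137897. Values after ± are the standard error (SE) for a log2 fold change and the SD over 2 libraries for library-scaled counts (CPM), and n = 2 libraries for each group mean.

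Dnmt3a (chromosome 12, 3806007 to 3914443, mm10), the gene named in the genotype label, was measured at 275 and 244 CPM in WT control numbers 1 and 2 and at 166 and 248 CPM in HET control numbers 1 and 2. After IL-6 it was at 175 and 183 CPM in WT and at 140.1 and 213 CPM in HET. The number 1 libraries labelled HET were below both WT libraries of their treatment, whereas HET control number 2 lay between the WT control libraries and HET IL-6 number 2 lay above both WT IL-6 libraries. By edgeR the log2 fold change of HET over WT was -0.32 ± 0.25 in control (adjusted p = 0.506), -0.02 ± 0.25 in IL-6 (adjusted p = 0.972) and -0.17 ± 0.17 averaged over treatment (adjusted p = 0.536). Leaving out both HET number 2 libraries, chosen after their values were seen, lowers the estimate by itself and is no test of Dnmt3a. It was then -0.64 in control, -0.35 in IL-6 and -0.50 averaged over treatment, and without both HET number 1 libraries it was -0.06, 0.25 and 0.10.

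**Figure D1:**
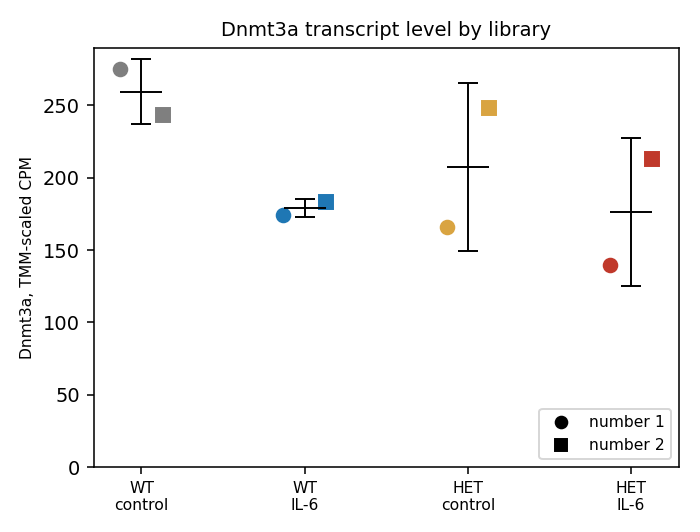
Dnmt3a transcript level in TMM-scaled CPM for each library (circle, number 1; square, number 2), with the mean and SD of each group of 2 libraries. The HET number 1 libraries sit at 166 and 140.1 CPM and the HET number 2 libraries at 248 and 213 CPM.

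Averaged over genotype, IL-6 raised the monocyte chemoattractant Ccl8 (chromosome 11, 82115185 to 82116799, mm10) by a log2 fold change of 5.33 ± 0.19, from 0.561 ± 0.107 to 12.5 ± 2.90 CPM in WT and from 0.320 ± 0.0806 to 24.4 ± 3.52 CPM in HET. The leukotriene B4 receptor gene Ltb4r1 rose by 4.94 ± 0.23, the chemokine receptor gene Ccr1 by 3.72 ± 0.10, podoplanin (Pdpn) by 3.79 ± 0.27, the metalloproteinase inhibitor Timp1 by 3.71 ± 0.17 and complement C4b by 3.19 ± 0.21. Ednrb, Lix1, Cd5l and Nxpe5 followed with log2 fold changes from 2.81 to 2.97. The largest falls were those of Apol9b (-3.75 ± 0.27), the interferon-induced Ifit3b (-2.79 ± 0.10), the sialic acid hydroxylase gene Cmah (-2.68 ± 0.10) and the immunoglobulin heavy chain gene Ighm (-2.44 ± 0.16), followed by Asb2, Egr3, Abcg3, Ifit3, Gbp6 and Tox2 at -2.34 to -2.09. Other genes overlap 29.0% of the exon bases of Gbp6, so its value is uncertain. The edgeR adjusted p of these 20 genes was at most 0.00103 (Cd5l), and all 20 stayed called without each library in turn and with the GC and length offsets.

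**Figure D2:**
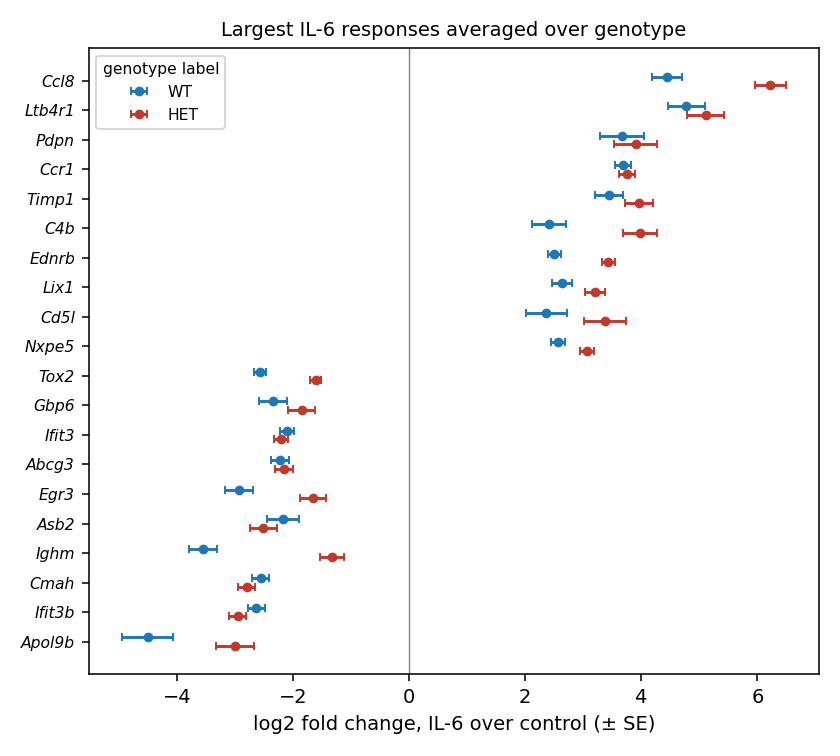
Log2 fold change of IL-6 over control (± SE, 2 libraries in each group) in WT and HET for the 20 genes with the largest rise or fall averaged over genotype. Each gene moved in the same direction in both genotypes, which the rule for naming them required, with Ccl8 at 4.44 in WT and 6.22 in HET.

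Among genes of the IL-6 pathway, the IL-4 receptor gene Il4ra (chromosome 7, 125552120 to 125579474, mm10), a known STAT3 target, rose by 2.69 ± 0.07 (edgeR adjusted p = 4.51e-12), Il21r by 0.75 ± 0.06, Stat3 itself by 0.56 ± 0.06 and Bcl3 by 0.63 ± 0.13, while the IL-6 receptor gene Il6ra fell (-0.42 ± 0.05). Socs3, which encodes a feedback inhibitor of the pathway, was at 0.06 ± 0.06 (adjusted p = 0.525) after 2 days and, with the GC and length offsets, at 0.15 ± 0.05 (adjusted p = 0.0270). Of the 22 measured members of the IL-6 and STAT3 list, 9 rose and 5 fell (9 higher and 5 lower adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.103). With the offsets 11 rose and 4 fell and camera adjusted p = 0.0494, and adjusted p = 0.541 with an estimated correlation. In HET alone 8 rose and 3 fell (8 higher and 3 lower adjusted over the list alone), where camera adjusted p = 0.00496, and adjusted p = 0.397 with an estimated correlation. In WT alone camera adjusted p = 0.732.

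The type I interferon-stimulated genes fell together: all 30 measured members fell, among them Ifit3b, Ifit3 (-2.15 ± 0.08), Cmpk2 (-1.61 ± 0.07) and Oas3 (-1.19 ± 0.06), with 0 higher and 30 lower adjusted over the list alone. The median of the list was -1.01. For type I interferon genes camera adjusted p = 3.52e-33, and adjusted p = 0.177 with an estimated correlation. Within the genotypes 30 of 30 fell in WT (median -1.09) and 28 in HET (median -0.91). MHC class I genes, which serve antigen presentation, fell in 17 of 18 members (0 higher and 17 lower adjusted over the list alone), with Tap1 at -0.63 ± 0.05, the immunoproteasome subunit gene Psmb9 at -0.71 ± 0.06 and H2-T23 at -0.63 ± 0.07. Their median was -0.44. For MHC class I camera adjusted p = 2.37e-11, and adjusted p = 0.348 with an estimated correlation. Genes of matrix remodelling rose in 15 of 21 members (15 higher and 1 lower adjusted over the list alone), with osteopontin (Spp1) at 1.82 ± 0.07, Mmp19 at 1.81 ± 0.07 and Timp1, while the urokinase gene Plau fell (-0.87 ± 0.06). The list median was 0.85. For matrix remodelling camera adjusted p = 2.13e-10, and adjusted p = 0.0871 with an estimated correlation. Glycolysis and glucose uptake genes rose in 15 of 19 members (15 higher and 1 lower adjusted over the list alone), with the glucose transporter gene Slc2a1 at 0.83 ± 0.06, the lactate exporter gene Slc16a3 at 0.88 ± 0.07 and Pdk1 at 0.64 ± 0.05. For glycolysis camera adjusted p = 1.33e-08, and adjusted p = 0.416 with an estimated correlation.

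Fc, complement and efferocytosis receptor genes rose in 8 of 19 members and fell in 1, Axl (11 higher and 1 lower adjusted over the list alone), led by the inhibitory Fc receptor gene Fcgr2b at 1.69 ± 0.07 and the integrin gene Itgax at 2.18 ± 0.10. For phagocytic receptors camera adjusted p = 3.92e-06, and adjusted p = 0.348 with an estimated correlation. Lysosomal genes rose in 10 of 26 (10 higher and 1 lower adjusted over the list alone), with cathepsin L (Ctsl) at 1.35 ± 0.06, while the lysosomal regulator Tfeb fell (-0.51 ± 0.09). For lysosomal genes camera adjusted p = 0.00149, and adjusted p = 0.526 with an estimated correlation. Genes of the unfolded protein and stress response rose in 6 of 19 (7 higher and 1 lower adjusted over the list alone), with Pdia4 at 0.35 ± 0.05 and Atf3 falling (-0.58 ± 0.08). For the stress response camera adjusted p = 0.00926, and adjusted p = 0.416 with an estimated correlation. It was 0.0989 without both HET number 1 libraries. Cholesterol synthesis genes fell in 18 of 24 (0 higher and 22 lower adjusted over the list alone, camera adjusted p = 2.13e-10, and adjusted p = 0.416 with an estimated correlation) and S phase, G2 and mitosis genes in 11 of 32 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 2.92e-04, and adjusted p = 0.526 with an estimated correlation), but both averages combine unlike responses of the genotypes, described below.

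**Figure D3:**
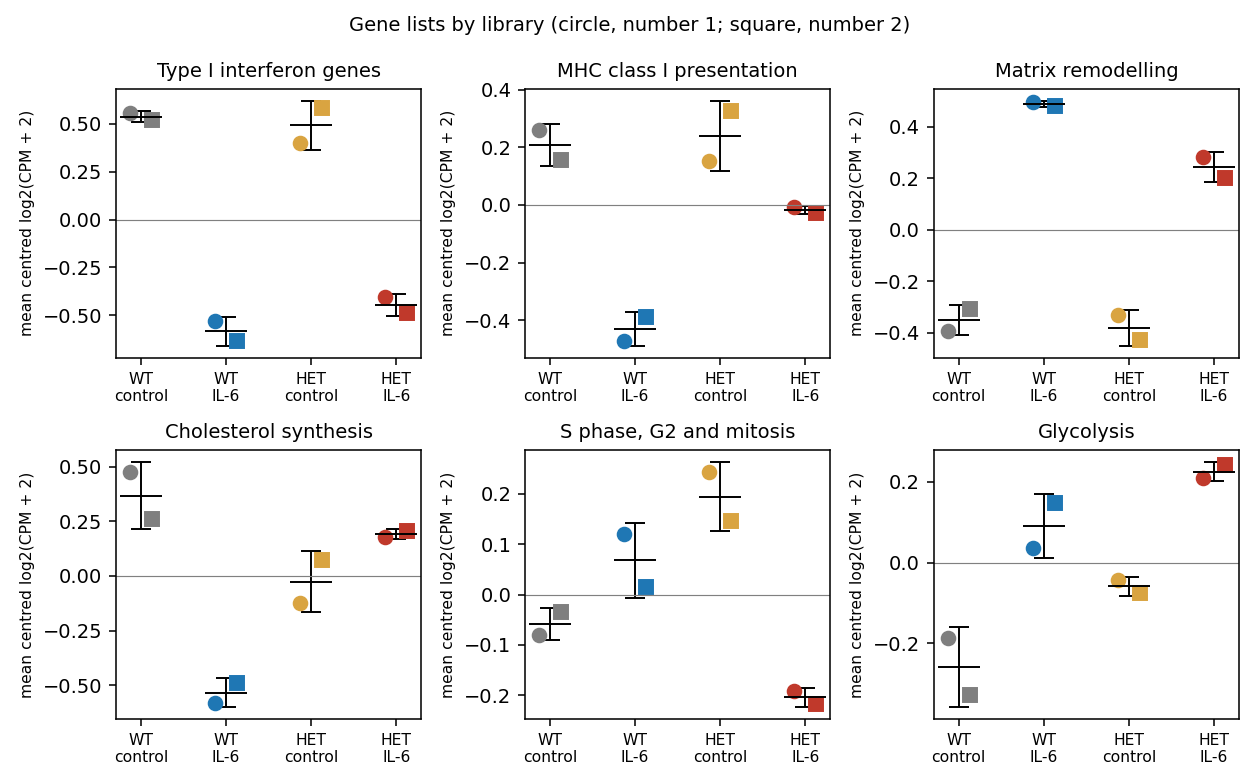
Mean of log2(CPM + 2), centred over the 8 libraries, of the tested genes of 6 lists in each library (circle, number 1; square, number 2), with mean and SD of each group of 2 libraries. Type I interferon and MHC class I genes sit lower after IL-6 in both genotypes, whereas cholesterol synthesis genes sit lower in WT and higher in HET.

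In total, edgeR called 3243 of 13721 tested genes for IL-6 against control averaged over genotype, 1484 higher and 1759 lower, of which 229 and 228 changed at least 2-fold. The GC and length offsets gave 4231, 2096 higher and 2135 lower. Higher genes were 45.8% of the calls with TMM and 34.8% with scaling to total counts. Without both HET number 2 libraries 1672 genes were called, and without both HET number 1 libraries 1699.

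In WT alone, IL-6 raised Ltb4r1 by 4.77 ± 0.32, Ccl8 by 4.44 ± 0.26, Ccr1 by 3.68 ± 0.14, Pdpn by 3.67 ± 0.38 and Sirpb1c by 3.46 ± 0.34. The largest falls were Ighm (-3.55 ± 0.25), the stearoyl-CoA desaturase gene Scd1 (-2.97 ± 0.46), Egr3 (-2.93 ± 0.24), Ifit3b (-2.63 ± 0.15) and Tox2 (-2.57 ± 0.11). Cholesterol synthesis genes fell in 23 of 24 members (0 higher and 23 lower adjusted over the list alone), with a median of -0.98 and with Cyp51 at -1.06 ± 0.09, Sc5d at -1.13 ± 0.09 and Mvk at -1.35 ± 0.12. For cholesterol synthesis camera adjusted p = 8.01e-24, and adjusted p = 0.227 with an estimated correlation. Lipid handling genes fell in 15 of 26 (1 higher and 16 lower adjusted over the list alone), including Srebf1 (-0.79 ± 0.10) and the fatty acid synthase gene Fasn (-0.77 ± 0.11), while the scavenger receptor gene Msr1 rose (1.58 ± 0.13). For lipid handling camera adjusted p = 1.72e-05, and adjusted p = 0.361 with an estimated correlation. Of the 32 cell cycle genes, 2 rose (1 higher and 0 lower adjusted over the list alone), Ccne1 (0.62 ± 0.10) and Rrm2 (0.34 ± 0.10). In this list camera adjusted p = 0.00448, adjusted p = 0.730 with an estimated correlation and camera adjusted p = 0.115 without WT IL-6 number 1. Fry did not call it (adjusted p = 0.144). Under the GC and length offsets 9 rose and 0 fell, and camera adjusted p = 0.00178.

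For WT, edgeR called 2515 genes, 1086 higher and 1429 lower, and with the GC and length offsets 3222, 1684 higher and 1538 lower. Without WT IL-6 number 1 the count was 1569, and Scd1 was not called without WT IL-6 number 1 (edgeR adjusted p = 0.136) or number 2 (edgeR adjusted p = 0.0812).

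In HET, IL-6 raised Ccl8 by 6.22 ± 0.27, Ltb4r1 by 5.11 ± 0.32, C4b by 3.97 ± 0.30, Timp1 by 3.96 ± 0.24 and Pdpn by 3.91 ± 0.37. The largest falls were Nptx1 (-3.48 ± 0.31), the lectin gene Cd207 (-3.12 ± 0.50), Apol9b (-2.99 ± 0.33), Ifit3b (-2.95 ± 0.14) and Cd300e (-2.82 ± 0.17). Cell cycle genes fell in 26 of 32 members (0 higher and 28 lower adjusted over the list alone), with a median of -0.47 and with Ccnb2 at -0.62 ± 0.08, Mcm6 at -0.50 ± 0.08 and Bub1b at -0.52 ± 0.08. For the cell cycle camera adjusted p = 4.01e-15, and adjusted p = 0.191 with an estimated correlation. Stress response genes rose in 9 of 19 (10 higher and 1 lower adjusted over the list alone), led by the asparagine synthetase gene Asns (1.27 ± 0.12), Trib3 (1.80 ± 0.19) and Sesn2 (0.79 ± 0.12). For the stress response camera adjusted p = 1.54e-04, and adjusted p = 0.191 with an estimated correlation. Cholesterol synthesis genes rose in 4 of 24 (5 higher and 0 lower adjusted over the list alone). For cholesterol synthesis camera adjusted p = 3.15e-04, and adjusted p = 0.587 with an estimated correlation. It was 0.0640 without HET control number 1. Lipid handling genes rose in 10 of 26 and fell in 1 (10 higher and 1 lower adjusted over the list alone), with the fatty acid binding protein gene Fabp5 at 1.73 ± 0.20 and the lipoprotein lipase gene Lpl falling (-0.66 ± 0.09). For lipid handling camera adjusted p = 0.00239, and adjusted p = 0.397 with an estimated correlation. Fry called neither cholesterol synthesis (adjusted p = 0.185) nor lipid handling (adjusted p = 0.0622) in HET.

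For HET, edgeR called 2508 genes, 1217 higher and 1291 lower, and with the offsets 3514, 1696 higher and 1818 lower. The count was 1198 without HET control number 1, 1476 without HET control number 2, 1329 without HET IL-6 number 1 and 1310 without HET IL-6 number 2. It was 789 without both HET number 2 libraries and 679 without both HET number 1 libraries.

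Across the 13721 genes, which are not independent replicates, the IL-6 responses of the genotypes, measured on separate libraries, had a Pearson r of 0.451. The genes called in both genotypes comprised 502 that rose in both, against 96.3 in the overlap of independent lists, and 508 that fell in both, against 134. Another 112 genes were called in opposite directions, against 229 in independent lists.

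Without IL-6, the genes that stood highest in HET over WT were Cd207 (2.57 ± 0.51, with 0.901 ± 0.598 CPM in WT and 5.30 ± 2.71 in HET) and Olfml3 (2.04 ± 0.29). The basement membrane collagen genes Col4a1 (chromosome 8, 11198423 to 11312826, mm10) and Col4a2 rose by 1.43 ± 0.13 and 1.22 ± 0.13, and Dmpk by 1.44 ± 0.20. Among the falls were the folate enzyme gene Aldh1l2 (-1.72 ± 0.25), the desaturase gene Scd2 (-1.36 ± 0.23), the acetyl-CoA synthetase gene Acss2 (-1.10 ± 0.17) and Cnrip1 (-1.01 ± 0.12). The stem cell factor receptor gene Kit was lower (-1.19 ± 0.27), and the rule took 10 further genes with log2 fold changes of 1.21 to 1.53 for rises and -1.14 to -0.90 for falls. Other genes overlap 14.1% of the exon bases of Aldh1l2. Of these 20 genes, Col4a1, Col4a2, Cnrip1 and Dmpk stayed called without each library in turn, and 12 stayed called with the GC and length offsets, which ended the calls of Cd207, Dmpk and Scd2 among those named here. Their values were then 2.61 ± 0.58, 1.25 ± 0.28 and -1.37 ± 0.26, so those of Cd207 and Scd2 kept their size while the standard error grew. The call of Cd207 was lost without WT control number 1 (edgeR adjusted p = 0.0973), WT control number 2 (0.0682), HET control number 1 (0.131) or HET IL-6 number 2 (0.0590), and that of Olfml3 without WT control number 1 (0.0544) or 2 (0.0574). That of Scd2 was lost without WT control number 1 (0.0680) or 2 (0.0512) or HET control number 1 (0.0948), and that of Kit without WT control number 1 (0.0985) or HET control number 1 (0.287). Without HET control number 1 the calls of Aldh1l2 (0.0702) and Acss2 (0.0948) were also lost.

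Cholesterol synthesis genes were lower in HET control than in WT control in 14 of 24 members (0 higher and 18 lower adjusted over the list alone), with a median of -0.42 and with Cyp51 at -0.62 ± 0.09, Sc5d at -0.62 ± 0.09 and Hmgcs1 at -0.53 ± 0.08. For cholesterol synthesis camera adjusted p = 2.93e-15, and adjusted p = 0.472 with an estimated correlation. Cell cycle genes were higher in 9 of 32 (18 higher and 0 lower adjusted over the list alone), with Mcm5 at 0.50 ± 0.08, Tk1 at 0.55 ± 0.10 and Aurkb at 0.44 ± 0.08. For the cell cycle camera adjusted p = 1.02e-12, and adjusted p = 0.472 with an estimated correlation. With the GC and length offsets 20 were higher and 0 lower. Glycolysis genes were higher in 5 of 19 (9 higher and 0 lower adjusted over the list alone), with Slc2a1 at 0.44 ± 0.09 and Eno1 at 0.41 ± 0.09. For glycolysis camera adjusted p = 1.09e-05, and adjusted p = 0.513 with an estimated correlation. Stromal and fibroblast markers were lower in 1 of 7 (0 higher and 1 lower adjusted over the list alone), at summed levels of 7.85 to 20.96 CPM in WT control and 3.51 to 5.16 CPM in HET control. For stromal markers camera adjusted p = 0.0199, and adjusted p = 0.611 with an estimated correlation. It was 0.306 without WT control number 2. Fry called 0 lists in this comparison, with adjusted p = 0.0573 for cholesterol synthesis. In the control arm edgeR called 666 genes, 385 higher and 281 lower in HET, with 31 changed at least 2-fold each way. With the offsets 653 were called, 321 higher and 332 lower, of which 369 had been called without them. In proportion to its size, the count of 666 ranged more than any other over the libraries left out. It was 1239 without WT control number 1, 421 without WT control number 2, 23 without HET control number 1, 157 without HET control number 2, 311 without HET IL-6 number 1 and 335 without HET IL-6 number 2. It was 172 without both HET number 2 libraries and 69 without both HET number 1 libraries.

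After IL-6, Scd1 was higher in HET than in WT by 2.66 ± 0.46 (5.71 and 7.82 CPM in the WT libraries, 52.9 and 32.6 in HET), Aldh1l2 by 2.40 ± 0.26, the serine synthesis gene Phgdh by 2.26 ± 0.32, Trib3 by 2.15 ± 0.20, Scd2 by 2.14 ± 0.24 and the stress cytokine gene Gdf15 (chromosome 8, 70629393 to 70632456, mm10) by 1.92 ± 0.14. The angiogenic factor gene Vegfa rose by 1.61 ± 0.23. The genes that stood lowest were Cd207 (-3.39 ± 0.50), Olfml3 (-2.10 ± 0.29), the integrin gene Itgal (-1.78 ± 0.27), the fractalkine receptor gene Cx3cr1 (-1.71 ± 0.31), Cd34 (-1.68 ± 0.21) and the VEGF receptor gene Flt1 (-1.56 ± 0.20), and the rule took 7 further genes with log2 fold changes of 1.67 to 1.70 for rises and -1.64 to -1.22 for falls. Aldh1l2, Scd2, Cd207, Olfml3, Itgal, Cd34 and Flt1 had been called in the opposite direction without IL-6. Of the 20 genes, 12 stayed called without each library in turn and 17 with the offsets, which ended the call of Cx3cr1 among those named here, at -1.76 ± 0.37 (edgeR adjusted p = 0.0587), with a larger standard error and no smaller change. Among the rises named here, Gdf15 shrank with the offsets to 1.40 ± 0.14, Trib3 to 1.76 ± 0.19, Phgdh to 1.92 ± 0.29 and Vegfa to 1.54 ± 0.26. Scd1, at 2.71 ± 0.52, Aldh1l2, at 2.45 ± 0.26, and Scd2, at 2.12 ± 0.27, stayed close to their values without them. Without WT IL-6 number 1 the calls of Scd1 (edgeR adjusted p = 0.199), Phgdh (0.0782), Vegfa (0.105), Itgal (0.104) and Cx3cr1 (0.166) were lost. That of Scd1 was also lost without WT IL-6 number 2 (0.0723) and that of Cx3cr1 without HET IL-6 number 2 (0.0866).

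Cholesterol synthesis genes were higher in HET IL-6 than in WT IL-6 in 23 of 24 members (23 higher and 0 lower adjusted over the list alone), with a median of 0.71 and with Mvk at 1.29 ± 0.12. For cholesterol synthesis camera adjusted p = 2.75e-18, and adjusted p = 0.448 with an estimated correlation. Lipid handling genes were higher in 14 of 26 and lower in 2, Msr1 and Lpl (16 higher and 3 lower adjusted over the list alone), with Srebf1 at 1.18 ± 0.10 and Fasn at 1.17 ± 0.11. For lipid handling camera adjusted p = 8.47e-06, and adjusted p = 0.448 with an estimated correlation. MHC class I genes were higher in 13 of 18 and Erap1 was lower (14 higher and 1 lower adjusted over the list alone), with Psmb10 at 0.72 ± 0.08 and H2-K1 at 0.58 ± 0.10. For MHC class I camera adjusted p = 6.89e-07, and adjusted p = 0.448 with an estimated correlation. Cell cycle genes were lower in 18 of 32 (0 higher and 20 lower adjusted over the list alone), with Ccnb1 at -0.48 ± 0.09 and Mki67 at -0.49 ± 0.09. For the cell cycle camera adjusted p = 8.06e-08, and adjusted p = 0.448 with an estimated correlation. Matrix remodelling genes were lower in 6 of 21 (0 higher and 6 lower adjusted over the list alone), with Mmp13 at -0.76 ± 0.11. For matrix remodelling camera adjusted p = 0.00321, and adjusted p = 0.448 with an estimated correlation. Beside them, marrow stromal and fibroblast markers were lower in 5 of 7 (0 higher and 5 lower adjusted over the list alone), at summed levels of 16.8 to 29.4 CPM in WT IL-6 and 5.37 to 10.6 CPM in HET IL-6. For stromal markers camera adjusted p = 0.00111, and adjusted p = 0.448 with an estimated correlation, and fry did not call them (adjusted p = 0.103).

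IL-6 and STAT3 genes were higher in 9 of 22 and lower in 1 (10 higher and 1 lower adjusted over the list alone), with Arid5a at 0.62 ± 0.09 and Junb at 1.21 ± 0.17 and with the survival factor gene Mcl1 lower (camera adjusted p = 0.00111, and adjusted p = 0.448 with an estimated correlation), and the call was lost with the GC and length offsets (camera adjusted p = 0.264), where 3 members were higher and 1 lower and Junb was at 0.64 ± 0.22 and not called. Socs3 was at 0.38 ± 0.09, Bcl3 at 0.58 ± 0.17 and Il4ra at 0.28 ± 0.09, and with the offsets at -0.03, 0.02 and -0.01. In the IL-6 arm edgeR called 3021 genes, 1814 higher and 1207 lower in HET, with 124 and 87 changed at least 2-fold. The count was 859 without WT IL-6 number 1, 1126 without HET IL-6 number 1, 965 without HET IL-6 number 2, 762 without both HET number 2 libraries, 996 without both HET number 1 libraries and 1616 with the offsets, 716 higher and 900 lower.

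Averaged over treatment, the genes that stood highest in HET were Dnaaf3 (1.18 ± 0.21), Dpm3 (1.02 ± 0.15), Amz1 (0.86 ± 0.10), the ribosomal protein gene Rpl36 (0.80 ± 0.12), Traf1 (0.76 ± 0.10) and the IL-3 receptor gene Il3ra (0.72 ± 0.08), followed by Thap3, Rplp1, Rnaseh2c and Bola2. Other genes overlap 24.8% of the exon bases of Rnaseh2c, so its value is uncertain. The lowest were Gpr34 (-0.67 ± 0.14), the Gt(ROSA)26Sor transcript (-0.63 ± 0.14), Cmah (-0.62 ± 0.10), Plod2 (-0.62 ± 0.13), Neo1 (-0.61 ± 0.17) and Plxdc2 (-0.59 ± 0.09), followed by Zxdb, the chemokine receptor gene Ccr2, Hmga2 and the mitochondrial tRNA gene mt-Tn. With the GC and length offsets 10 of the 20 stayed called, Dpm3, Amz1, Traf1, Il3ra, Bola2, Cmah, Plod2, Plxdc2, Zxdb and Hmga2. Of the lost calls, that of Neo1 kept its size, at -0.60 ± 0.18 (edgeR adjusted p = 0.141), while the changes of all the others shrank. The call of Gpr34 was lost without WT IL-6 number 1 (edgeR adjusted p = 0.0616), that of Gt(ROSA)26Sor without HET control number 2 (0.0539) and that of Ccr2 without WT control number 2 (0.133) or WT IL-6 number 1 (0.0687). That of Neo1 was lost without WT control number 1 (0.0756), WT IL-6 number 1 (0.0859) or 2 (0.0698), HET control number 2 (0.0839) or HET IL-6 number 2 (0.0792).

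MHC class I genes were higher in HET in 11 of 18 members (14 higher and 2 lower adjusted over the list alone), with Psmb10 at 0.49 ± 0.06 and Tap2 at 0.51 ± 0.06. For MHC class I camera adjusted p = 4.19e-05, and adjusted p = 0.646 with an estimated correlation. With the GC and length offsets 2 members were higher and 0 lower, and the median went from 0.24 to 0.10, while the list stayed called (camera adjusted p = 6.70e-04). Glycolysis genes were higher in 8 of 19 (10 higher and 0 lower adjusted over the list alone), with Pfkl at 0.37 ± 0.06. For glycolysis camera adjusted p = 2.04e-04, and adjusted p = 0.646 with an estimated correlation. It was 0.0598 with the offsets, where 2 members were higher and 0 lower and Pfkl was at 0.12 ± 0.05 (edgeR adjusted p = 0.212). Stromal markers were lower in 4 of 7 (0 higher and 4 lower adjusted over the list alone), with Bgn at -2.06 ± 0.35 and Sparc at -2.21 ± 0.45. For stromal markers camera adjusted p = 7.03e-04, and adjusted p = 0.646 with an estimated correlation. With the offsets 0 members were higher and 1 lower and Sparc was at -2.33 ± 0.56 (edgeR adjusted p = 0.0958), but the median went from -1.57 to -1.77 and camera adjusted p = 1.19e-05. IL-6 and STAT3 genes were higher in 8 of 22 (8 higher and 1 lower adjusted over the list alone), with Junb at 0.78 ± 0.12 and Il4ra at 0.34 ± 0.06. For IL-6 and STAT3 genes camera adjusted p = 0.00208, and adjusted p = 0.646 with an estimated correlation. It was 0.167 with the offsets, where 0 members were higher and 1 lower, with Junb at 0.41 ± 0.16 (edgeR adjusted p = 0.273) and Il4ra at 0.11 ± 0.04 (edgeR adjusted p = 0.192). Cholesterol synthesis genes were higher in 6 of 24 (10 higher and 0 lower adjusted over the list alone), with Mvk at 0.57 ± 0.08. This average combines opposite differences described above, lower in HET control and higher in HET IL-6, and does not describe either treatment. For cholesterol synthesis camera adjusted p = 0.00239, and adjusted p = 0.737 with an estimated correlation. It was 0.0930 without HET control number 2 and 0.0903 without both HET number 2 libraries, and with the offsets 2 members were higher and 0 lower, with a median of 0.13 against 0.12 and camera adjusted p = 1.22e-07. Fry called 0 lists averaged over treatment, with adjusted p from 0.0871 for MHC class I to 0.194 for cholesterol synthesis among these.

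The difference between the genotypes followed the GC content of genes. The median deviation of the fifth of genes highest in GC minus that of the fifth lowest in GC was 0.19, 0.19, 0.23 and 0.27 on the log2 scale in the HET libraries and 0.06, -0.30, -0.47 and -0.18 in the WT libraries. The 3 WT libraries below 0 also had a larger share of mitochondrial counts, 1.36% to 1.59% against 1.13% to 1.29% in the other 5, and a smaller share of ribosomal protein counts, 2.43% to 2.54% against 2.701% to 2.828%. Averaged over treatment edgeR called 2729 genes, 1633 higher with a median GC content of 56.9% and 1096 lower with a median of 42.2%, of which 22 and 45 changed at least 2-fold. With each library's trend on GC content and exon length removed, 331 genes were called, 175 higher and 156 lower, and 226 of them had been called without the offsets.

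**Figure D4:**
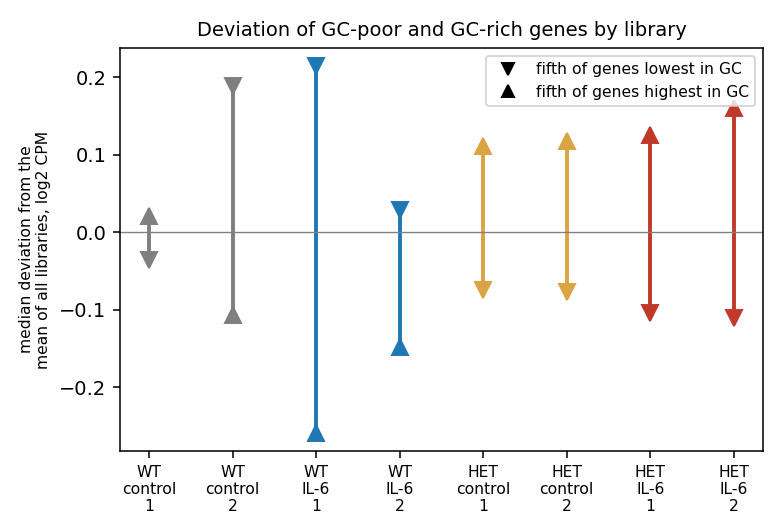
Median deviation from the mean of all libraries, in log2 CPM, of the fifth of tested genes lowest in GC content and the fifth highest, for each library. The fifth highest in GC lies above the fifth lowest in all HET libraries and in WT control number 1 and below it in the other WT libraries.

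The count for HET against WT averaged over treatment was 4507 without WT control number 1, 1548 without WT control number 2, 1128 without WT IL-6 number 1, 1193 without HET control number 1, 1029 without HET control number 2, 1208 without HET IL-6 number 1 and 953 without HET IL-6 number 2. It was 376 without both HET number 2 libraries and 664 without both HET number 1 libraries.

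The IL-6 response itself differed between the genotypes. Scd1, which fell with IL-6 in WT (-2.97), was at 1.86 in HET, a difference of 4.83 ± 0.63 (edgeR adjusted p = 0.0154), and the differences were 4.11 ± 0.36 for Aldh1l2, 3.49 ± 0.34 for Scd2, 3.28 ± 0.44 for Phgdh and 2.82 ± 0.28 for Trib3. In the other direction Cd207, at 2.85 in WT and -3.12 in HET, differed by -5.96 ± 0.71 (edgeR adjusted p = 0.00103), Olfml3 by -4.14 ± 0.41, Itgal by -3.30 ± 0.38, Cx3cr1 by -3.05 ± 0.43 and Nptx1 by -2.97 ± 0.43. The Il6 transcript, low in all groups, was at 1.31 ± 0.231 CPM in WT control, 0.659 ± 0.0540 in WT IL-6, 0.620 ± 0.0107 in HET control and 3.56 ± 1.77 in HET IL-6, a difference of responses of 3.47 ± 0.58 (edgeR adjusted p = 0.00272). All 10 genes stayed called with the GC and length offsets, and Aldh1l2, Scd2, Trib3, Cd207 and Olfml3 stayed called without each library in turn. The call of Scd1 was lost without WT IL-6 number 1 (edgeR adjusted p = 0.118) or 2 (0.0697) or HET control number 1 (0.0881) or 2 (0.0534), and those of Phgdh (0.0606) and Itgal (0.0609) without WT IL-6 number 1. That of Cx3cr1 was lost without WT control number 1 (0.0720) or WT IL-6 number 1 (0.102) or 2 (0.0540) and that of Nptx1 without WT control number 1 (0.0783) or 2 (0.0517).

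**Figure D5:**
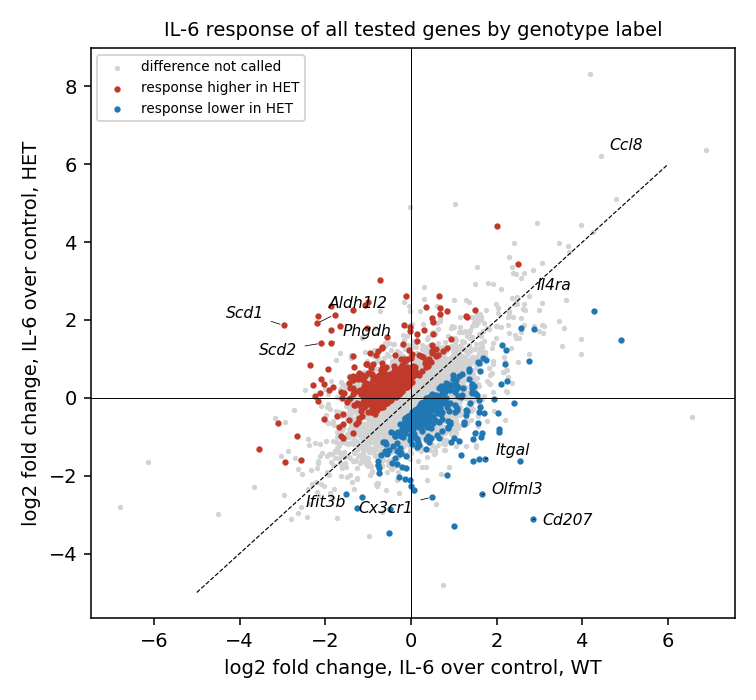
Log2 fold change of IL-6 over control in WT (horizontal) and HET (vertical) for the 13721 tested genes, coloured where the response differed between the genotypes (620 higher and 494 lower in HET). The dashed line marks equal responses, on which Il4ra lies close, while Scd1 and Cd207 lie far from it on opposite sides.

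For cholesterol synthesis genes the response was higher in HET in 23 of 24 members (23 higher and 0 lower adjusted over the list alone), with a median difference of 1.21 and with Cyp51 at 1.28 ± 0.12 and Sc5d at 1.34 ± 0.13. For cholesterol synthesis camera adjusted p = 1.30e-31, and adjusted p = 0.269 with an estimated correlation. Cell cycle genes had a lower response in HET in 25 of 32 (0 higher and 27 lower adjusted over the list alone), with a median of -0.59 and with Cdk1 at -0.69 ± 0.11 and Mcm6 at -0.62 ± 0.11. For the cell cycle camera adjusted p = 1.22e-21, and adjusted p = 0.269 with an estimated correlation. Lipid handling genes had a higher response in 13 of 26 and a lower one in 1, Msr1 (15 higher and 3 lower adjusted over the list alone), with Fasn at 1.34 ± 0.15 and the cholesterol exporter gene Abca1 at 1.39 ± 0.19. For lipid handling camera adjusted p = 6.97e-09, and adjusted p = 0.269 with an estimated correlation. MHC class I genes had a higher response in 8 of 18 (10 higher and 0 lower adjusted over the list alone), with H2-K1 at 0.63 ± 0.14. For MHC class I camera adjusted p = 2.21e-05, and adjusted p = 0.402 with an estimated correlation. Stress response genes had a higher response in 7 of 19 and a lower one in 2, the chaperone genes Calr and Creld2 (10 higher and 4 lower adjusted over the list alone), with Asns at 1.95 ± 0.16 and Sesn2 at 1.37 ± 0.18. For the stress response camera adjusted p = 0.0174, and adjusted p = 0.329 with an estimated correlation. H2-K1 and other MHC class I genes share sequence, so reads may have been divided among them and their single values are uncertain.

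By edgeR the response differed for 1114 genes, 620 higher and 494 lower in HET. Of these, 112 were called in both genotypes in opposite directions, 49 in the same direction with the larger change in HET, 48 in the same direction with the larger change in WT, 417 in HET alone, 414 in WT alone and 74 in neither. The count was 716 without WT control number 1, 2102 without WT control number 2, 607 without WT IL-6 number 1, 298 without HET control number 1, 654 without HET control number 2, 411 without HET IL-6 number 1 and 463 without HET IL-6 number 2. It was 399 without both HET number 2 libraries, 161 without both HET number 1 libraries and 1758 with the offsets, 766 higher and 992 lower, which kept 967 of the 1114 calls.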

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

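Of the tests in this part, those of GC content, depth, culture state, exchanged labels, counting error and splits within each treatment were chosen only after the result was seen, while the test for mislabelled HET number 2 libraries and the 35 splits of all libraries were chosen before it.

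The IL-6 response of 1114 genes differed between the genotypes by the edgeR test of the difference itself, which is what singled out every result in this paragraph. On the log2 scale, HET minus WT, the named genes differed by 4.83 for Scd1, 4.11 for Aldh1l2, 3.49 for Scd2, 3.28 for Phgdh, 2.82 for Trib3, -5.96 for Cd207, -4.14 for Olfml3, -3.30 for Itgal, -3.05 for Cx3cr1 and -2.97 for Nptx1. Of the cytokine and receptor genes fixed beforehand, Il6 differed by 3.47, Ccl2 by 0.57, Il1b by -1.16 and the IL-6 signal transducer gene Il6st by 0.38. The call of Ccl2 was lost without HET control number 1 (edgeR adjusted p = 0.0884) or HET IL-6 number 1 (0.0647). That of Il1b was lost without WT control number 1 (0.230) or 2 (0.0852), WT IL-6 number 1 (0.0638) or 2 (0.102) or HET IL-6 number 1 (0.0630) or 2 (0.0527). With the GC and length offsets Il1b went from -1.16 ± 0.25 to -1.15 ± 0.34 (edgeR adjusted p = 0.114), so its call ended because its standard error grew. The call of Il6st was lost without WT control number 1 (0.0907), WT IL-6 number 1 (0.117) or 2 (0.0620), HET control number 1 (0.245) or 2 (0.0890) or HET IL-6 number 1 (0.153) or 2 (0.191). The libraries that decide the other calls and the count of 1114 genes are named with the comparison itself.

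By camera at the preset correlation 11 lists had a response that differed between the genotypes. Their median differences were 1.21 for cholesterol synthesis, 0.64 for lipid handling, -0.59 for the cell cycle, 0.33 for MHC class I, 0.30 for the unfolded protein response, 0.26 for lysosomes, 0.16 for type I interferon, 0.23 for phagocytic receptors, -0.35 for MHC class II, -0.35 for matrix remodelling and -1.31 for the 5 measured neutrophil markers, of which S100a9 (-2.50 ± 0.53) and Mmp8 (-1.31 ± 0.33) had a lower response. With an estimated correlation the adjusted p of these lists was 0.269 to 0.683. The call of the type I interferon list was lost without WT IL-6 number 2 (camera adjusted p = 0.145), HET control number 1 (0.220) or HET IL-6 number 1 (0.0742) and without both HET number 1 libraries (0.547). That of MHC class II was lost without WT control number 2 (0.0790), WT IL-6 number 2 (0.0933), HET control number 2 (0.162) or HET IL-6 number 1 (0.0685) and without both HET number 2 libraries (0.160). That of matrix remodelling was lost without WT control number 1 (0.0593), WT IL-6 number 2 (0.0595), HET control number 1 (0.101) or HET IL-6 number 2 (0.0831), without both HET number 1 libraries (0.0504), with the number as a block (0.0515) and with the GC and length offsets (0.0761). That of phagocytic receptors was lost without WT control number 1 (0.0785), WT IL-6 number 1 (0.217), HET control number 1 (0.0859) or 2 (0.0559) or HET IL-6 number 1 (0.131), and without both HET number 1 (0.237) or both HET number 2 libraries (0.0582). It was also lost with the number (0.0830) or genotype and number (0.102) as a block, the stricter filter (0.0829) and the offsets (0.212). Fry did not call the type I interferon (adjusted p = 0.340), MHC class I (0.0679), MHC class II (0.142), lysosomal (0.142) and phagocytic receptor lists (0.153).

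Averaged over treatment, 2729 genes differed between HET and WT, and their GC content differed by direction. With each library's trend on GC content and exon length removed 331 genes were called, so a GC trend of the libraries is a candidate explanation for most of the calls; Rpl36, for example, went from 0.80 ± 0.12 to 0.47 ± 0.19, so its fold shrank and its standard error grew. In both fits 226 genes were called, but both used the same libraries, and these genes were picked by staying called. The offsets remove only a smooth trend, so this number does not decide whether a difference in preparation lies behind them. The tables argue against depth for the count, since 2482 genes were called with all libraries thinned to the smallest total. A difference in RNA or library preparation between the genotypes and a genotype effect on GC-rich genes both stay open, as no label gives a batch. A biological effect of the genotype was not tested apart from them.

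Among the 18 splits that keep 2 libraries of each treatment on each side, the real genotype split called 920 genes and the highest other 105. The real split was the 1 that called as many, and 18 splits are too few for a share under 0.05. The split with 105 set WT control and HET IL-6 against the other groups, which is the difference of responses itself. The remaining splits mixed the genotypes and held any genotype difference in their spread, which lowers their counts. These 18 splits therefore do not exclude chance. In the 35 splits of all 8 libraries into 4 and 4, fitted without treatment, edgeR called 0 genes for genotype (2569 at an unadjusted p under 0.05), so all 35 called as many, and the highest other, 1408, was the split by IL-6. For IL-6 against control 1 of 35 splits, the real one, called as many as its 1408 genes, against 12 for the highest other. The other splits were fitted without treatment and held the IL-6 effect in their spread, which lowers their counts. The test could therefore hardly favour another split and does not exclude chance. For lists chance cannot be excluded: 12 of 35 splits called as many as the 8 of IL-6 against control (highest other 11), and 32 of 35 as many as the 2 of HET against WT (highest other 11).

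The difference of the IL-6 response between the genotypes held groups of genes that moved in opposite directions, such as cholesterol synthesis and the cell cycle. Of the 1114 genes, 967 were called both with and without the offsets, which argues against a smooth GC and length trend as the source for these genes. The offsets remove only such a trend, and both fits used the same libraries. They do not decide whether a difference in preparation between libraries lies behind the difference of responses. A culture state that varies between libraries, such as density, could give such groups. Over the called genes the difference between the libraries of a group followed the interaction with slopes of 0.17 in WT control, -0.08 in WT IL-6, -0.11 in HET control and 0.06 in HET IL-6. The largest slope lies between what was set for and against this state. Pearson r over these genes was 0.70, -0.38, -0.50 and 0.34 in the same order. Each difference was number 1 minus the other library of the group. The signs are those with which the groups enter the interaction, so in every group number 1 lay further along it. The interaction was computed from these same libraries and the genes were picked by it, so slopes and r may be partly built in. They therefore cannot decide for or against a culture state. Genotype labels exchanged in 1 treatment arm could also give opposite genotype differences: with the offsets 250 genes were called in opposite directions, against 38.4 in independent lists, but r across all tested genes was -0.08, and this test replaced a first one on r alone after r was seen. Without the offsets r was 0.08, and 117 genes were called in opposite directions, against 71.0. In the same fit 110 were higher in HET in both arms, against 50.9, and 19 lower in both, against 24.7. These counts hold the GC trend. Culture state and exchanged labels both stay open, as does a difference in preparation. An effect of the genotype on the response also stays open and was not tested apart from them.

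In the libraries labelled HET number 2, Dnmt3a lay between the WT libraries in control and above both in IL-6, at 1.49 times number 1 in control and 1.52 times in IL-6. A test against counting error decided nothing: the lower 95% bound of this ratio was 1.43 in the smaller arm, but the WT libraries also differed by more than counting error, with a ratio of 0.885 (0.854 to 0.917) in control and 1.05 (1.003 to 1.099) in IL-6. A wrong label of the HET number 2 libraries could not be settled: r across tested genes between HET over WT of number 1 and of number 2, with the offsets, was 0.22, between the bounds of 0.1 and 0.3 set for and against it for the average of both treatments. It was 0.215 in control and 0.384 in IL-6, and 0.407 averaged with the GC trend left in place. On the second principal component of all tested genes, HET IL-6 numbers 1 and 2 lay at 27.2 and 21.5 and WT IL-6 at -26.1 and -15.8. On the third, HET control lay at 22.2 and 15.3 and WT control at -18.4 and -20.2. Number 2 thus lay beside number 1, but these components also hold the GC trend and any difference in preparation, so they do not settle the label. A mouse-to-mouse difference in the Dnmt3a transcript, or an allele that leaves the transcript in place, may also give these values, and neither was tested because the labels give neither the allele nor the mouse of a library.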

How the results depend on the processing

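The settings with GC and length offsets, thinning, HET libraries of 1 number left out, crossed pairing and total-count scaling were chosen only after the data were seen; the others were planned. With RLE scaling, DESeq2, the stricter filter of 11613 genes, thinning to 18926641 counts and total-count scaling, each of the 7 counts of called genes stayed within 1.5 times its value. In IL-6 against control averaged over genotype this gave 3056 (thinned) to 3427 genes (total counts), and in HET against WT in control 608 (thinned) to 832 (DESeq2). Without a filter, on 26592 genes, HET against WT in control gave 1078. A fit to the 2 groups compared gave 3907 for IL-6 in HET, against 2508 with the spread taken over all groups.

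With GC and length offsets HET against WT gave 1616 genes in IL-6 and 331 averaged over treatment, and the difference of responses 1758. Socs3 turned to -0.033 and Il4ra to -0.0073 in HET against WT in IL-6. Without both HET number 2 libraries the counts were 1672 for IL-6 averaged over genotype, 789 for IL-6 in HET, 172, 762 and 376 for HET against WT in control, in IL-6 and averaged, and 399 for the difference of responses. The lists called for HET against WT in IL-6 were then 11, Dnmt3a was at -0.64 in control and -0.50 averaged, and the r of the responses was 0.333. With the offsets as well, the counts were 1464 for IL-6 in HET and 166, 406 and 13 for HET against WT in control, in IL-6 and averaged. Dnmt3a was at -0.71, -0.42 and -0.56 in these, and Socs3 (-0.076 in IL-6, -0.055 averaged), Bcl3 (-0.15 in IL-6) and Il4ra (-0.091 in IL-6) changed sign. Without both HET number 1 libraries the counts were 1699 for IL-6 averaged, 679 for IL-6 in HET, 69, 996 and 664 for HET against WT, and 161 for the difference, with 8 lists for HET against WT averaged. With the offsets as well they were 1248 for IL-6 in HET, 0 (edgeR, with 1414 genes at an unadjusted p under 0.05), 341 and 39 for HET against WT, and 287 for the difference. The cause of these changes was not tested.

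Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 1569 to 3069 genes for IL-6 in WT, 1198 to 3062 for IL-6 in HET, 23 to 1239 for HET against WT in control, 859 to 3998 in IL-6, 953 to 4507 averaged and 298 to 2102 for the difference of responses. The library behind the lowest of each of these counts is named with its comparison. Those behind the highest counts for IL-6 in WT, IL-6 in HET and HET against WT in IL-6 are not named. For lists, HET against WT gave 7 to 11 in IL-6 (11 without HET IL-6 number 2) and 4 to 8 averaged (8 without HET control number 1). The r of the responses was 0.370 to 0.462, and IL-6 averaged over genotype gave 2331 to 3524 genes.

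With an estimated correlation camera called 0, 0, 0, 0, 0, 0 and 0 lists in the 7 comparisons, with 0 to 5 lists at an unadjusted p under 0.05. Fry called 0 lists for HET against WT in control (7 unadjusted), 0 averaged over treatment (9 unadjusted) and 7 for the difference, and camera at the preset correlation had called 9, 5 and 11.

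The library numbers did not establish a pairing: the deviations of same-numbered libraries correlated at -0.11 in WT and 0.15 in HET. These deviations held the GC trend, which in WT ran opposite ways by number. The fifth highest in GC minus the lowest was 0.06 and -0.30 in WT control numbers 1 and 2 and -0.47 and -0.18 in WT IL-6. The check therefore cannot decide for or against a pairing in WT. With the number as a block HET against WT in control gave 339 genes and the difference of responses 732. With genotype and number as a block the difference gave 506, and Socs3 turned to 0.20 in WT when the offsets were added. As a random block in limma (consensus correlation -0.306) HET against WT averaged gave 4455 and the difference 518, and with the counts of same-numbered libraries summed HET against WT averaged gave 4266. Neither fit used the offsets, with which the main fit called 331 genes for HET against WT averaged. In WT the sums join GC trends of 0.06 with -0.47 and of -0.30 with -0.18, so they differ less in this trend than single libraries. The larger counts therefore add no support for a genotype effect. No other count of genes or lists under these blocks moved by over 1.5 times. A crossed pairing of WT gave 5144 genes for IL-6 averaged, 4443 in WT, 4435 in HET and 3121 for the difference. The cause of these changes was not tested.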

Other observations

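All tests in this part used lists fixed before the data were examined. Among chemokines after IL-6, averaged over genotype, the monocyte chemoattractants Ccl12 and Ccl7 rose by 2.53 ± 0.07 and 0.92 ± 0.06, whereas the interferon-inducible Cxcl10 fell (-1.25 ± 0.07). The proinflammatory list went both ways, 8 of 28 rising and 11 falling (10 higher and 11 lower adjusted over the list alone), and did not pass (camera adjusted p = 0.939). Among alternative activation genes the mannose receptor gene Mrc1 rose by 1.22 ± 0.06 and Cd200r1 by 0.67 ± 0.05, while the haemoglobin scavenger receptor gene Cd163 (-0.82 ± 0.07) and Irf4 (-1.19 ± 0.12) fell, with 2 of 15 higher and 5 lower (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.780). The haem oxygenase gene Hmox1 rose by 0.98 ± 0.06 and Slc7a11 by 0.83 ± 0.11, within an NRF2 list of which 5 of 17 rose and 6 fell (5 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.780). Of the osteoclast genes 1 of 15 rose and 3 fell (5 higher and 4 lower adjusted over the list alone), with the transcription factor gene Nfatc1 at -0.32 ± 0.05 (camera adjusted p = 0.789). Of the MHC class II genes 2 of 13 rose and 3 fell (2 higher and 3 lower adjusted over the list alone), with H2-Aa at -0.28 ± 0.07 (camera adjusted p = 0.272).

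In HET against WT averaged over treatment, 4 of 18 genes of DNA methylation were higher and 1 lower (5 higher and 1 lower adjusted over the list alone), with Mbd3 at 0.49 ± 0.06 and Gadd45b at 0.49 ± 0.07 (camera adjusted p = 0.188). With the GC and length offsets 0 were higher and 1 lower, and Mbd3 was at 0.11 ± 0.05 (edgeR adjusted p = 0.269) and Gadd45b at 0.24 ± 0.07 (edgeR adjusted p = 0.0935). After IL-6 averaged over genotype 3 rose and 4 fell (3 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.512). Of the respiratory chain genes 8 of 29 were higher and 1 lower in HET averaged over treatment (9 higher and 2 lower adjusted over the list alone), with Uqcrq at 0.66 ± 0.07, and the list did not pass. With the offsets 2 were higher and 0 lower, and Uqcrq was at 0.64 ± 0.07. In HET against WT in control camera called the respiratory chain list (adjusted p = 0.0226, and adjusted p = 0.611 with an estimated correlation), but the call was lost without WT control number 2 (0.306) or HET control number 1 (0.0760), without both HET number 1 libraries (0.0965) and by fry (0.211).

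Markers of macrophage identity moved both ways after IL-6 averaged over genotype, 3 of 16 rising and 2 falling (3 higher and 4 lower adjusted over the list alone), with the transcription factor gene Maf at -0.47 ± 0.06, and their summed level was 19444 to 21195 CPM over all libraries. Of the monocyte markers 3 of 9 rose and 3 fell (3 higher and 3 lower adjusted over the list alone), with Ly6a at 1.44 ± 0.10 and Nr4a1 at -0.72 ± 0.07. The platelet factor gene Pf4 rose by 0.97 ± 0.06, 1 of 7 megakaryocyte markers. Neutrophil markers summed to 3.27 to 13.8 CPM, with Mmp8 rising by 1.53 ± 0.16, 1 of 5, and dendritic cell markers to 3.78 to 8.20 CPM, with Kmo and Ccr7 rising by 1.45 ± 0.14 and 1.42 ± 0.47, 2 of 5. Camera adjusted p in this comparison was 0.219 for dendritic cells, 0.296 for neutrophils, 0.583 for megakaryocytes and 0.789 for macrophages and for monocytes alike. In WT alone 2 of 5 neutrophil markers rose (2 higher and 0 lower adjusted over the list alone), at a median of 1.06 against -0.41 in HET. For neutrophils in WT camera adjusted p = 0.0383, and adjusted p = 0.322 with an estimated correlation. It was 0.0636 without WT control number 1, 0.0875 without WT control number 2, 0.0931 without WT IL-6 number 2 and 0.0527 with the offsets.

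Lists with fewer than 5 measured markers were not tested as lists. B cell markers summed to 41.9 to 61.5 CPM in WT control and 4.42 to 6.81 CPM in WT IL-6, and to 31.5 to 32.3 CPM in HET control and 13.0 to 13.5 CPM in HET IL-6, most of it Ighm, whose response was higher by 2.23 ± 0.33 in HET (edgeR adjusted p = 0.00333). Of the mast cell and basophil markers, which summed to 5.77 to 13.7 CPM over all libraries, Hdc fell (-1.35 ± 0.22) averaged over genotype. Kit fell in WT (-2.12 ± 0.30) and was at 0.12 ± 0.28 in HET (edgeR adjusted p = 0.824), and Il4 was at 0.67 ± 0.24 in WT (edgeR adjusted p = 0.0665) and rose by 2.30 ± 0.26 in HET, with edgeR adjusted p = 0.00498 for the difference of the responses of Kit and 0.0130 for that of Il4. Of the endothelial markers, at 37.3 to 61.6 CPM, Kdr rose by 0.85 ± 0.07 averaged over genotype, and Flt1 was at 0.08 ± 0.18 in WT (edgeR adjusted p = 0.823) and fell in HET (-2.37 ± 0.19), with edgeR adjusted p = 1.72e-04 for the difference. The erythropoietin receptor gene Epor, the measured member of the erythroid list, fell (-1.69 ± 0.38) at 0.587 to 1.46 CPM. Of the T and NK cell markers, at 1.07 to 5.46 CPM, Cd4 fell in WT (-2.48 ± 0.65) and was at 0.20 ± 0.58 in HET (edgeR adjusted p = 0.864) and at -1.14 ± 0.44 averaged over genotype (edgeR adjusted p = 0.0931), with Lck at 0.11 ± 0.33 (edgeR adjusted p = 0.850). Adipocyte markers were below the filter, at a summed level of at most 0.126 CPM.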
